A study of Mus musculus with 18 samples.

How the data were processed

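Ribosome footprints and mRNA were measured in cortical neurons of C57BL/6 mouse embryos. Per the labels' protocols, MTOR constructs were electroporated into the cortex in utero at embryonic day 14, and the electroporated neurons were sorted by flow cytometry at embryonic day 18. Footprints are the stretches of mRNA that ribosomes shield from RNase I, and they were purified on a size-exclusion column, while mRNA was fragmented by heat, per the labels' protocols. Both kinds of fragment went through the same small RNA kit, and the labels mention no molecular identifiers, so reads from the same molecule cannot be told apart. The labels give 6 groups of 3 libraries, which are footprints and mRNA for each of the constructs WT, C1483Y and L2427P.

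The submitters' processing notes name Bowtie 1.1.2, TopHat2 2.1.1, HTSeq without a version and the genome build mm10. Which tool was used for which kind of library, the annotation and the strand setting are not given in the sources used here. For 17 libraries the authors deposited whole-number counts per gene symbol. The deposited values of footprint library C1483Y replicate 3 are treated as estimated counts, because 165 of them are not whole, and they were rounded. Every deposited count of footprint library WT replicate 3 is a multiple of 3, and 97.7% of the values above 0 of footprint library C1483Y replicate 3 are multiples of 4, by steps that no label records. Each file names 24035 genes. A further 27 names had been turned into dates by a spreadsheet and were left out. They held 0.172% to 0.267% of the counts in the footprint libraries other than C1483Y replicate 3, and 0.0935% to 0.328% of the mRNA counts. The 5 summary values at the end of each file were left out of library sizes and tests. They are empty in footprint library C1483Y replicate 1. In the others, reads outside any gene made up 4.34% to 14.7% of all counts in a file in the footprint libraries and 7.06% to 14.1% in the mRNA libraries, and reads that were not aligned uniquely made up 9.05% to 29.5% and 49.9% to 77.5%. The lowest footprint shares, 4.34% and 9.05%, are those of C1483Y replicate 3, and they are uncertain because its values are displaced, as described below. Without that library the footprint shares were 8.43% to 14.7% and 21.9% to 29.5%.

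The order of the genes in each file was tested by matching windows of 300 consecutive genes with the mean of the footprint libraries at a range of offsets. The tested library and footprint library C1483Y replicate 3 were left out of that mean, which also served for the mRNA files. In footprint library C1483Y replicate 3 the tested windows matched best without an offset up to Cyb5rl, the gene at position 5400, and at an offset afterwards. Position 5400 is a window edge, so the displacement may start within a neighbouring window. Windows with few expressed genes were not tested, and the first tested window starts at position 1801. Genes up to position 5400 are taken below as those before the displacement. That library was left out of the footprint and translational efficiency fits, and no attempt was made to realign its names. This departs from the design fixed before the data were examined, which had all 9 footprint libraries and all 18 libraries in those fits. The fits with all libraries are given beside the results.

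Genes were kept by edgeR's filterByExpr with a minimum count of 10, and in both assays for translational efficiency. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion and Benjamini-Hochberg adjustment at 0.05. The mRNA fit had 9 libraries, the footprint fit 8 and the translational efficiency fit 17. Translational efficiency is the footprint level relative to the mRNA level and was tested as the interaction of assay and genotype in a model over both kinds of library. In each assay and for translational efficiency, each mutant was compared with WT, the mean of both mutants with WT, and L2427P with C1483Y, which makes 12 contrasts. A further contrast, footprint level against mRNA level averaged over the genotypes, was added after the data were examined. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. Levels of single genes are CPM, the usual scaling of a count by the library's total over the named genes. For the genes always given, both mutants were compared with WT by exact two-sided permutation tests on log2(CPM + 1).

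A total of 29 gene lists was fixed before the data were examined, as were the contrasts, most of the other settings tried and the rule for naming genes. The lists cover translation, mTOR signalling, metabolism, organelles, stress, the cell cycle, neuronal genes and markers of 9 cell types. The list of mitochondrially encoded proteins had 0 of its 13 members in the files and was not tested. Lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, with adjustment over 328 tests in the genotype contrasts and over 27 in the added contrast. Where members are said to pass over the list alone, the adjustment covered only that list in that contrast. It was not extended over the 328 and 27 pairs of list and contrast, so some such passes can be chance. The naming rule takes up to 10 genes per direction with the largest change among called genes above the median expression in each contrast of a mutant with WT, without predicted genes and pseudogenes, and up to 4 members per list with the smallest p. It was applied in the same form to the added contrast. Mtor, Adk and the markers Bcl11b, Pax6, Eomes, Gad1, Gfap, C1qa, Cldn5 and Hbb-bs are always given. Some genes that the rule takes are not reported here.

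Alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors in edgeR, TMM within each assay, no filter on low counts, the compared groups alone, a block for the replicate number, a block for the library pair, and each library left out in turn. After the data were examined, fits with the displaced library, on the genes before the displacement, on abundant genes (log2 CPM above 8) and with footprint library WT replicate 3 divided by 3 were added. The list tests of the added contrast were repeated with DESeq2 size factors and with TMM within each assay, also after the data were examined. Tables and exact intervals were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

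The fits were tested on simulated counts in which a random set of genes was changed by known folds of 2, 4 and 16, at the spread between replicates seen in the files. Of genes changed 2-fold, 0% were recovered in each mRNA and footprint contrast and at most 1.56% in the translational efficiency contrasts. Of genes changed 16-fold, 14.5% to 22.6% were recovered in the mRNA contrasts, 3.13% to 14.3% in the footprint contrasts, 0% to 4.76% in the translational efficiency contrasts and 33.3% in the added contrast. In the mRNA contrasts 12 of 62 calls fell on unchanged genes, and in the added contrast 10 of 35, which is above the 5% aimed at. For the footprint contrasts 0 of 23 calls and for translational efficiency 0 of 8 calls fell on unchanged genes. When the ribosomal protein list was lowered 2-fold in L2427P mRNA, camera gave p = 4.39e-06, and p = 0.00192 with an estimated correlation, and 1 of 26 other lists had p below 0.05. Simulated genes varied independently, whereas the estimated correlation of this list was 0.458 in the real contrast of L2427P with WT mRNA. These simulated p-values therefore do not show that a 2-fold shift of the list would be found in the real data.

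Total counts ranged from 7695442 to 34094913 in the footprint libraries and from 18627076 to 53283035 in the mRNA libraries. A count of 0 allows up to 3 counts, which is 0.0880 to 0.390 CPM in the footprint libraries and 0.0563 to 0.161 CPM in the mRNA libraries. The lowest footprint floor and the highest footprint total are those of WT replicate 3, whose counts are all multiples of 3. If its counts were multiplied, its floor is given too low and its total too high. Intervals and floors cover counting error only. The labels do not say that libraries of a group came from separate litters, so p-values measure only the spread between these samples, which may be partly technical. Biological coefficients of variation were 2.25 in the mRNA fit, 2.02 in the footprint fit and 2.07 in the joint fit. Genes with near-identical copies, ribosomal protein genes with their pseudogenes above all, have uncertain counts, because how reads with several matches were treated is not given. Overlapping and antisense genes are uncertain in the same way.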

Results

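The libraries compare cortical neurons that carried wild-type MTOR (WT) or MTOR with the amino acid substitution C1483Y or L2427P. MTOR is the kinase of the mTOR complexes, which control protein synthesis, and mutations of it are found in focal malformations of cortical development, the disorder that the series title abbreviates as FMCD. The comparison asks which mRNAs and which ribosome footprints differ between the genotypes. Each of the 6 groups, footprints and mRNA for 3 genotypes, had 3 libraries. Footprint libraries held 7695442 to 34094913 counts on 6112 to 10941 genes, and mRNA libraries held 18627076 to 53283035 counts on 3173 to 11661 genes. The highest footprint total is that of WT replicate 3, whose counts are all multiples of 3, so its depth may be overstated.

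Many abundant genes were missing from some libraries. Of the 5000 most abundant genes, 52.6% had a count of 0 in mRNA library L2427P replicate 3 and 22.1% in mRNA library C1483Y replicate 3. Among the footprint libraries used below the share was highest in WT replicate 1, at 16.4%. Mean shares were 6.17% ± 7.19 (SD, n = 3) in WT mRNA, 9.34% ± 11.2 (SD, n = 3) in C1483Y mRNA and 19.8% ± 28.6 (SD, n = 3) in L2427P mRNA, so the spread within groups was as large as the differences between them. In footprint library C1483Y replicate 3 the values were displaced against the gene names in 51 of 63 windows, and the library was not used in the fits below.

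**Figure D1:**
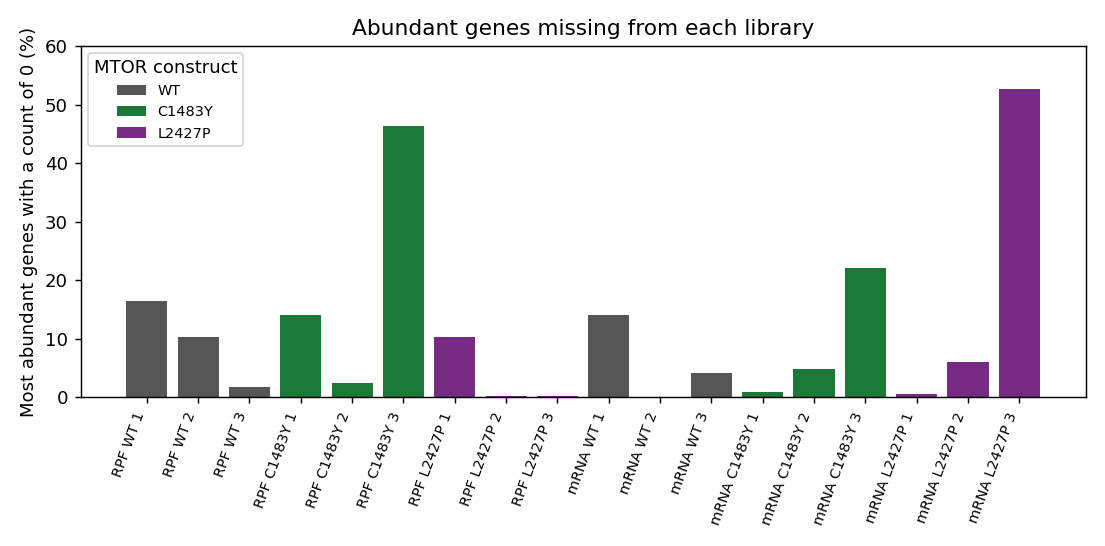
Percent of the 5000 most abundant genes with a count of 0 in each of the 18 libraries, with 1 bar per library coloured by MTOR construct. The highest bars are mRNA L2427P replicate 3 at 52.6% and footprint (RPF) C1483Y replicate 3 at 46.3%, whose values are displaced against the gene names.

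**Figure D2:**
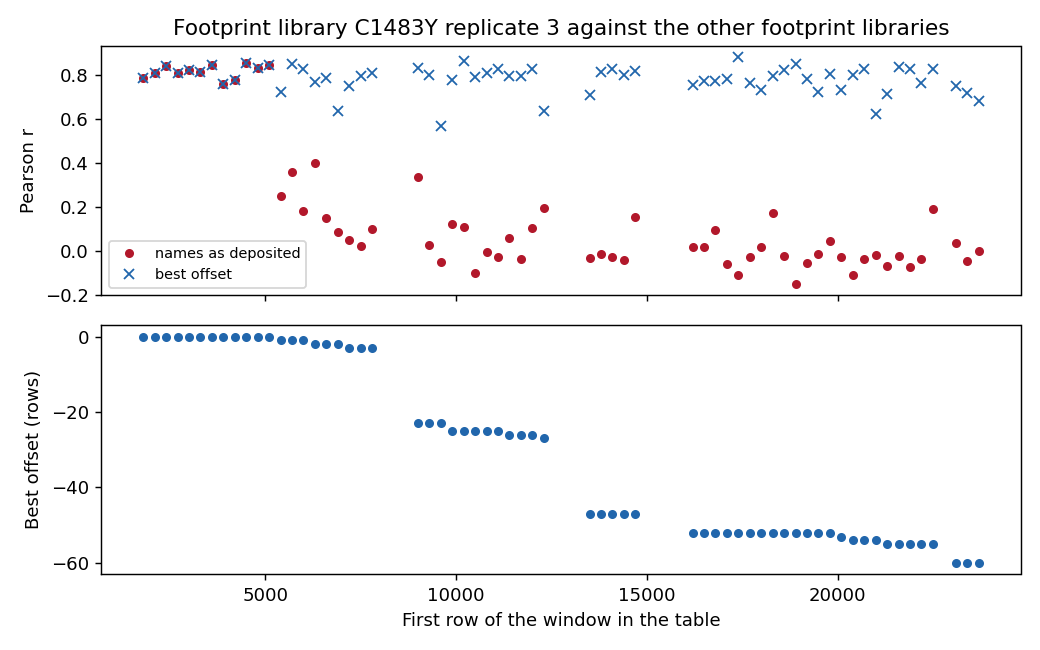
Upper panel, Pearson correlation of footprint library C1483Y replicate 3 with the other footprint libraries in windows of 300 genes, plotted against the first gene position of the window, for names as deposited and at the best offset. Lower panel, the best offset in gene positions, which is 0 up to position 5400 and reaches -60 at the end of the file.

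Mtor, the electroporated gene, was checked first. Its annotated locus is chromosome 4, 148448582 to 148557685 (GRCm38, the assembly of mm10), and its counts may include reads from the construct, which cannot be separated here. Mtor footprints averaged 3618 ± 611 CPM (SD, n = 3) in WT and 2160 ± 848 CPM (SD, n = 5) in the mutants, and every mutant library lay below every WT library. The exact two-sided permutation test gave p = 0.0357, the smallest that 5 against 3 libraries allow, and 0.393 after adjustment over 22 such tests. Mtor mRNA averaged 570 ± 103 CPM (SD, n = 3) in WT and 443 ± 203 CPM (SD, n = 6) in the mutants (exact permutation p = 0.262).

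Adk encodes adenosine kinase, the enzyme that phosphorylates adenosine, and lies on chromosome 14, 21052574 to 21448569. Its footprints were at 0, 20.1 and 8.36 CPM in the WT libraries and at 61.3 to 92.8 CPM in the 5 mutant libraries. The means were 9.48 ± 10.1 CPM (SD, n = 3) and 72.5 ± 12.9 CPM (SD, n = 5), a ratio of 7.65. Every mutant library was above every WT library, with an exact two-sided permutation p = 0.0357, the smallest possible, and 0.393 after adjustment over 22 tests. Adk mRNA averaged 31.6 ± 27.4 CPM (SD, n = 3) in WT and 18.5 ± 20.5 CPM (SD, n = 6) in the mutants (exact permutation p = 0.262). These means mix detected and missing values. Adk mRNA had 0 counts in C1483Y replicates 2 and 3 and L2427P replicate 3, and 1 count in WT replicate 3. It lay at 30.8 to 47.7 CPM in the other mRNA libraries. By edgeR's quasi-likelihood test the Adk footprint difference of both mutants from WT was 2.98 on the log2 scale (SE 3.12, adjusted p = 0.982), which did not pass the threshold.

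**Figure D3:**
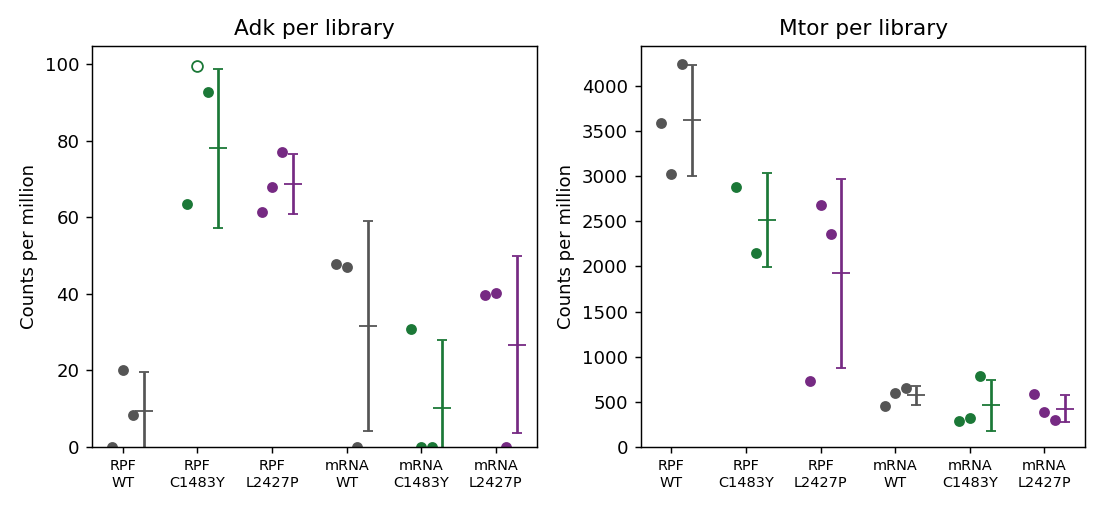
CPM of Adk and Mtor in each library by assay and MTOR construct, with the mean ± SD of each group beside its points; the open circle is Adk in the displaced footprint library, which is not in the mean. All 5 mutant footprint libraries lie above the WT libraries for Adk and below them for Mtor.

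Among the marker genes, footprints of the deep-layer marker Bcl11b averaged 125 ± 68.9 CPM in WT (SD, n = 3) and 71.3 ± 66.4 CPM in the mutants (SD, n = 5). Footprints of the progenitor markers averaged 41.4 ± 37.9 CPM in WT and 54.7 ± 50.9 CPM in the mutants for Pax6, and 237 ± 80.8 and 177 ± 115 CPM for Eomes. Markers of other cell types were present in some libraries too. Gad1, an interneuron marker, averaged 0.0587 ± 0.102 and 3.04 ± 5.22 CPM, Gfap, an astrocyte marker, 26.8 ± 45.1 and 5.96 ± 8.13 CPM, and C1qa, a microglial marker, 40.5 ± 44.6 and 65.4 ± 84.2 CPM, each as footprints in WT (SD, n = 3) and in the mutants (SD, n = 5). C1qa footprints were thus at about the level of Pax6, and reached 198 CPM in C1483Y replicate 1. Gad1 footprints were near the floor in WT, at 0, 0 and 0.176 CPM, and their mutant mean rested on L2427P replicate 3 at 12.3 CPM. Gad1 mRNA averaged 19.4 ± 33.3 CPM in WT (SD, n = 3) and 13.6 ± 23.2 CPM in the mutants (SD, n = 6). In mRNA, C1qa averaged 60.5 ± 88.3 CPM in WT (SD, n = 3) and 73.7 ± 54.8 CPM in the mutants (SD, n = 6), above Pax6 at 11.5 ± 10.3 and 29.8 ± 37.5 CPM, and Gfap reached 281 CPM in L2427P replicate 3. The endothelial marker Cldn5 was at 35.6 CPM in mRNA library L2427P replicate 1 and had 0 or 1 counts in each of the other mRNA libraries, and it had 0 footprint counts. Among erythroid genes, Hbb-bs, a haemoglobin gene, had 0 counts in either assay, but Fech, an enzyme of haem synthesis, had footprints at 0.0866 ± 0.150 CPM in WT (SD, n = 3), 87.1 ± 123 CPM in C1483Y (SD, n = 2) and 20.6 ± 18.2 CPM in L2427P (SD, n = 3), and Alas2, of the same pathway, at 0.0433 ± 0.0750, 0 and 10.1 ± 8.85 CPM. The Fech level in C1483Y came from 1 library at 174 CPM, with the other at 0.185 CPM. The erythroid list, with 3 of 14 members tested in footprints, had a median of 9.76 in C1483Y against WT (limma's camera, adjusted p = 0.785) and of 7.54 in L2427P against WT, or 7.43 with members that had a group at 0 at their bound (camera p = 0.0172, adjusted p = 0.479, and p = 0.194 with an estimated correlation). Exact permutation tests of Bcl11b, Pax6, Eomes, Gad1, Gfap, C1qa and Cldn5 gave p of 0.143 or more in both assays.

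At the mRNA level, several ribosomal protein genes were lower in L2427P than in WT, although the list as a whole was not called. The 78 members tested had a median log2 fold change of -0.61, against -0.28 for all genes and -0.31 for the 672 abundant genes. Rpl5 was at 1571 ± 398 CPM in WT and 710 ± 265 CPM in L2427P (SD, n = 3 each), with a log2 fold change of -1.43 (SE 0.35). Rplp0 was at -1.04 (SE 0.27), Rpl36 at -1.48 (SE 0.41) and Rpl3 at -1.02 (SE 0.29). These 4 members passed when adjusted over the list alone (edgeR, adjusted p of Rpl5 = 0.00381), and 0 passed over all genes. Eef2, the elongation factor that moves the ribosome along the mRNA, was the 1 member of the other TOP translation genes that passed over its list alone, at -0.84 (SE 0.26, adjusted p = 0.0337, edgeR). By camera the ribosomal protein list had p = 0.00119 and an adjusted p of 0.196, and p = 0.500 with an estimated correlation. The count of 4 rested on single libraries: it was 0 without mRNA library WT replicate 1, 13 without L2427P replicate 1 and 1 without L2427P replicate 3, the library with 52.6% of abundant genes at 0. The list median minus that of all genes was -0.34, but 0.13 without L2427P replicate 1 and 0.22 with the replicate number as a block.

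In tests over 9558 genes, edgeR called 0 mRNAs between C1483Y and WT (152 at unadjusted p below 0.05, DESeq2 172 calls), 0 between L2427P and WT (231, DESeq2 288) and 0 between both mutants and WT (214, DESeq2 269). Chance alone gives 478 at unadjusted p below 0.05. Between L2427P and C1483Y edgeR called 1 gene, 2310014L17Rik, at a log2 difference of 2.48 (adjusted p = 0.000492). It falls outside the naming rule and was chosen after its values were seen, as the only call. There were 356 genes at unadjusted p below 0.05, and DESeq2 called 502. The gene lost its call in 5 of 14 alternatives with an adjusted p (7.74e-05 to 1). Among them, the log2 difference was 1.34 (adjusted p = 1) without L2427P replicate 3, the library where the gene stood at 4763 CPM, 2.28 (adjusted p = 0.0715) without C1483Y replicate 3 and 2.76 (adjusted p = 1) with DESeq2 size factors. Without L2427P replicate 1, edgeR called 3 genes in L2427P against WT, 2 for both mutants and 3 between the mutants. Without WT replicate 1, WT replicate 3 or L2427P replicate 2 it called 2 between the mutants, and without WT replicate 1 or L2427P replicate 2 it called 1 in C1483Y against WT. The median standard error of abundant genes was 0.68, so that 2-fold changes of most genes were not detectable at this spread.

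At the footprint level, Mtor was the gene nearest to the threshold. It was lower in L2427P than in WT by a log2 fold change of -1.04 (SE 0.24), with an adjusted p of 0.107 over 10315 genes (edgeR) and 0.000311 adjusted over the list alone of mTOR pathway components, where it was the 1 member of 30 that passed. In both mutants it was at -0.80 (SE 0.21, adjusted p = 0.791, over the list alone 0.00348). Hsp90aa1, a cytosolic chaperone, was lower in C1483Y at -0.85 (SE 0.25), with 1984 ± 383 CPM (SD, n = 2) against 3434 ± 771 CPM (SD, n = 3), and passed over the list of chaperones alone (adjusted p = 0.0163, edgeR) but not over all genes (0.71). Ribosomal protein footprints in L2427P against C1483Y had camera p = 0.000236, an adjusted p of 0.0775, and an adjusted p of 1 with an estimated correlation. Their median was -0.15 and their mean 0.07, which differ in sign. The median was 0.55 for all genes but 0.0090 for the 701 abundant genes, so the list lay much nearer to the abundant genes than to all genes. It passed with DESeq2 size factors (adjusted p = 0.0121) and without a filter on low counts (adjusted p = 0.025), but in both the adjusted p was 1 with an estimated correlation, and with the replicate number as a block the adjusted p was 0.567.

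EdgeR called 0 footprint differences between C1483Y and WT (454 at unadjusted p below 0.05, DESeq2 804), between L2427P and WT (388, DESeq2 288), between both mutants and WT (458, DESeq2 702) and between L2427P and C1483Y (131, DESeq2 504), where chance gives 516. With the displaced library as deposited, edgeR also called 0 in each, with 879, 444, 724 and 441 genes at unadjusted p below 0.05. Leaving out C1483Y replicate 2, which leaves 1 C1483Y library assumed to vary like the others, gave 153 calls against WT, 152 for both mutants and 125 between the mutants. Mtor in L2427P passed without WT replicate 2 (adjusted p = 0.0163) and without L2427P replicate 2 (adjusted p = 0.0379), with 0.0163 to 1 over its alternatives. Much of its change rested on L2427P replicate 1, at 730 CPM against 2681 and 2360 CPM in replicates 2 and 3. Without replicate 1 the log2 fold change was -0.75 (edgeR, adjusted p = 0.56). Without WT replicate 3, edgeR called 1 gene in each of the 4 contrasts, and without L2427P replicate 1 it called 1 in L2427P against WT and 1 between the mutants, where it also called 1 without L2427P replicate 3.

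For translational efficiency, the list members nearest to the threshold over all genes were 2 ribosomal protein genes. Rps19 was higher in both mutants than in WT by 6.76 on the log2 scale (SE 1.45), as its footprints averaged 1.12 ± 1.26 CPM in WT (n = 3), 92.0 ± 86.5 CPM in C1483Y (n = 2) and 49.9 ± 22.2 CPM in L2427P (n = 3), with SDs. Rpl41 differed between L2427P and C1483Y by 3.27 (SE 0.72), with C1483Y as the low group. Its footprints averaged 152 ± 133 CPM in WT (SD, n = 3), 16.4 ± 8.09 CPM in C1483Y (SD, n = 2) and 158 ± 75.7 CPM in L2427P (SD, n = 3). Against WT, Rpl41 was at -3.00 (SE 0.72) in C1483Y and at 0.27 (SE 0.65) in L2427P. Over all 8876 genes neither gene passed by edgeR (adjusted p = 0.0977 for Rps19, and 0.0542 between the mutants and 0.262 in C1483Y against WT for Rpl41), and all 3 differences passed when adjusted over the list alone (0.000848, 0.00047 and 0.00228). Eef2 was higher in L2427P than in WT by 1.38 (SE 0.42, edgeR adjusted p = 0.0164 over the list alone). Slc32a1, a vesicular transporter of inhibitory neurons, passed over the interneuron list alone in L2427P (adjusted p = 0.0117, edgeR), but with groups at 0, so that no fold is given. Ribosomal protein genes have near-identical copies elsewhere in the genome, so the counts of Rps19 and Rpl41 are uncertain.

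EdgeR called 0 genes in translational efficiency for C1483Y against WT (334 at unadjusted p below 0.05, DESeq2 805), L2427P against WT (375, DESeq2 541), both mutants against WT (320, DESeq2 478) and L2427P against C1483Y (371, DESeq2 875), where chance gives 444. With the displaced library as deposited the counts were 0, with 426, 299, 336 and 444 genes at unadjusted p below 0.05. Leaving out footprint library C1483Y replicate 2 gave 31 calls for C1483Y against WT, 27 between the mutants and 3 for both mutants. Without footprint library WT replicate 3 there were 2, 1, 2 and 4 calls for C1483Y against WT, between the mutants, for both mutants and for L2427P against WT, and leaving out any mRNA library gave at most 3 in any of the contrasts. Between the mutants 1 gene was called without WT replicate 1, WT replicate 2 or L2427P replicate 3 of the footprint libraries. The median standard error of abundant genes was 1.45 in C1483Y against WT and 1.36 in L2427P against WT. Rps19 passed over all genes without mRNA library L2427P replicate 3 (adjusted p = 6.2e-09, with 6.2e-09 to 1 over its alternatives) and without each other mRNA library, and in none of the fits without 1 footprint library. In all it passed in 13 of 26 alternatives. Among the passes were DESeq2's Wald test, DESeq2 size factors, no filter on low counts and the replicate block. It did not pass with the library pair block, TMM within each assay or abundant genes alone. Between the mutants Rpl41 passed in 9 of 27 alternatives, with adjusted p of 0.000201 to 1. In C1483Y against WT it passed in 5 of 27, with adjusted p of 0.00325 to 1, and was at -1.90 without footprint library WT replicate 1.

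Over all 12 genotype contrasts, 0 of 328 list tests passed by camera with the preset correlation, by camera with an estimated correlation or by fry, and 27 had an unadjusted camera p below 0.05. The markers of 9 cell types took part in 100 of these tests, of which 10 had p below 0.05. Deep-layer neuron genes came closest, in C1483Y against WT mRNA (limma's camera, adjusted p = 0.258), with a median of -6.25, or -4.72 with the 3 of 8 members that had a group at 0 placed at their bound. Of these genes Pcp4, a calmodulin-binding protein of deep-layer neurons, was at 67.2 ± 24.7 CPM in WT mRNA (SD, n = 3) and at 0 in all 3 C1483Y libraries, and passed over the list alone for both mutants (adjusted p = 0.019, edgeR). Single members that passed over a list alone, here and above, were not adjusted over the 328 pairs of list and contrast, so some can be chance. The list of Adk and other adenosine genes had 11 members tested in footprints, of which 0 passed in L2427P against WT (limma's camera, adjusted p = 0.59).

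The last comparison, footprint level against mRNA level averaged over the genotypes, was fitted after the data were examined. Ribosomal protein genes were low in footprints relative to mRNA, with a median log2 ratio of -2.23 for 77 members against -0.32 for all genes, and 50 members were lower over all genes and 64 adjusted over the list alone, with 0 higher in either. Rpl41 was at -4.93 (SE 0.35), Rps7 at -3.45 (SE 0.33), Rpl13a at -3.34 (SE 0.35) and Rps14 at -3.12 (SE 0.33). Rps7, for example, had 114 ± 100 CPM of footprints and 2453 ± 721 CPM of mRNA in WT (SD, n = 3 each). By camera the list had an adjusted p of 1.29e-36, and an adjusted p of 0.0612 with an estimated correlation. Fry gave an adjusted p of 0.000234. With DESeq2 size factors or TMM within each assay the adjusted p with an estimated correlation was 0.00493 and 0.0444. The direction held with DESeq2 size factors (median -2.03) and with TMM within each assay (median -2.47). Reads not aligned uniquely made up 21.9% to 29.5% of counts in the footprint libraries of this fit that hold the value, and 49.9% to 77.5% in mRNA. How such reads were treated is not given, and ribosomal protein genes have near-identical copies. A mapping difference between the assays therefore cannot be told apart from a low footprint level per mRNA. Other differences between the assays, such as how the fragments were made, were not tested and stay open too.

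For genes of neuronal migration and the cytoskeleton the median was 0.72 for 39 members, with 13 higher and 2 lower over all genes, and 14 and 3 adjusted over the list alone. The 712 abundant genes of this fit had a median of 0.42, against -0.32 for all genes, so the list lay nearer to the abundant genes than to all genes. Map1b, a microtubule-associated protein of growing axons, was at 3.57 (SE 0.18, edgeR adjusted p = 1.79e-81), with 6095 ± 1205 CPM of footprints and 614 ± 113 CPM of mRNA in WT (SD, n = 3 each). Ncam1, a neural cell adhesion molecule, was at 2.19 (SE 0.30), Cfl1, an actin-severing protein, at 2.08 (SE 0.31), and Stmn1, a microtubule-destabilising protein, at -1.06 (SE 0.16). Synaptic vesicle genes had a median of 0.63, and 3 of 23 members were higher over all genes and 4 over the list alone, with Snap25 at 5.65 (SE 1.58), Pclo at 5.37 (SE 1.6) and Syt11 at 2.30 (SE 0.69). Epilepsy and neurodevelopmental disorder genes had a median of 0.66, with 2 of 32 members higher over all genes and 3 over the list alone, among them Snap25. The median was 1.1 for radial glia genes, with 0 of 16 members passing, -0.75 for the respiratory chain, with 2 of 74 lower over all genes and 3 over the list alone (Cox4i1 -1.71, Atp5e -3.08), and -1.20 for the mitochondrial ribosome, with 0 of 71 passing. These 7 lists passed by camera with the preset correlation (adjusted p = 1.29e-36 to 0.0253), and 0 lists passed with an estimated correlation, where the others had adjusted p of 0.704 to 0.913. The remaining 20 lists had adjusted p of 0.0567 to 0.848.

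Of the genes called in this contrast by edgeR, 148 were higher in footprints and 100 lower, 248 in all, with 1252 at unadjusted p below 0.05, and DESeq2 called 1617. The split moved with the scaling, to 105 higher and 133 lower with TMM within each assay. The 10 genes with the largest positive ratios were Snord57, Snora61, Erdr1, Tfg, Atn1, BC068157, Iglon5, Sf3a2, Cachd1 and Sf3b4, at 6.94 to 10.37 on the log2 scale without Snora61, Tfg and Sf3a2, which had a group entirely at 0. Snord57 and Snora61 are small nucleolar RNA genes, which encode no protein. The 10 with the largest negative ratios were Hist1h3e, Snord17, Cdc42se2, Egln2, Snn, Inpp5f, Ptp4a2, Pank3, Agpat6 and Rps19, at -7.57 to -5.33 without Hist1h3e, which had a group entirely at 0. All 20 were at 0 in at least 1 library, so these fitted ratios are not bounds. Snn and Snora61 were called in all of their 26 and 25 alternatives. The call was lost in 17 of 25 for Inpp5f, 16 of 23 for Hist1h3e, 16 of 27 for Cachd1, 12 of 27 for Agpat6, 11 of 25 for each of Ptp4a2 and Tfg, and 1 to 8 for the other 12 genes. In simulated counts 10 of 35 calls of this contrast fell on unchanged genes. With the displaced library as deposited 36 genes were called, and without mRNA library L2427P replicate 3 382 were.

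**Figure D4:**
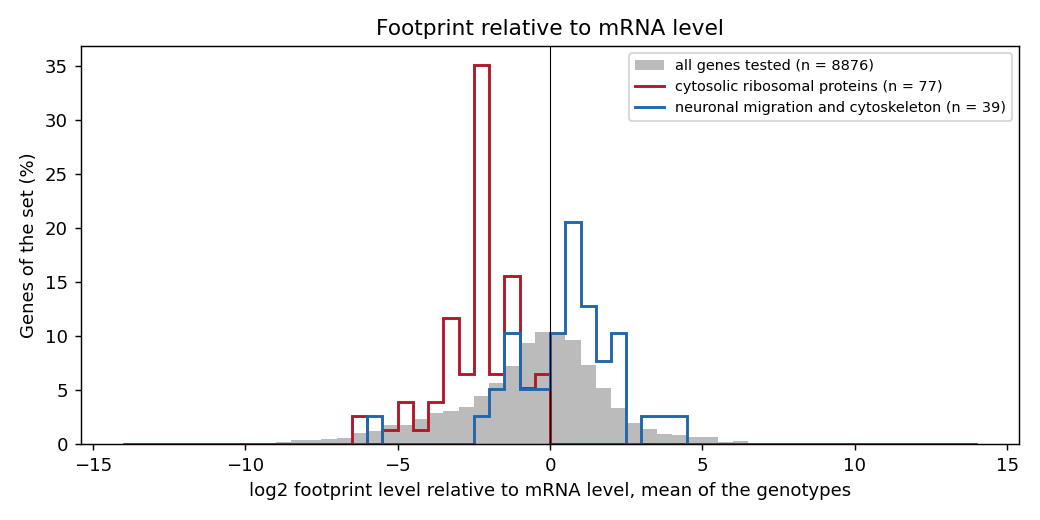
Share of genes in percent against the log2 footprint level relative to the mRNA level, averaged over the genotypes, for all 8876 genes tested, 77 cytosolic ribosomal protein genes and 39 genes of neuronal migration and the cytoskeleton. The median is -0.32 for all genes, -2.23 for ribosomal protein genes and 0.72 for migration and cytoskeleton genes, and it is 0.42 for the 712 abundant genes, which are not drawn.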

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

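The tests of explanations for the displaced library, for the ribosomal protein mRNAs and of the Adk mRNA level were chosen only after the result was seen, while the share of genes that behave like Adk and the counts over other splits of the libraries were written down before.

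Footprint library C1483Y replicate 3, left out of the comparisons, had a signal above the WT libraries for Adk, at 99.5 CPM, at a position where its values still match their gene names. In mRNA libraries C1483Y replicate 3, L2427P replicate 2 and L2427P replicate 3 the reads that were not aligned uniquely made up 71.1%, 64.5% and 77.5% of all counts in the file, above the 56.4% to 62.4% of the WT mRNA libraries. The share was 49.9% and 53.4% in C1483Y replicates 1 and 2, below the WT libraries, and 60.7% in L2427P replicate 1, among them, so that the group means were 58.1% in C1483Y, 67.6% in L2427P and 59.0% in WT. The mRNA of 2310014L17Rik differed between the mutants by 2.48 on the log2 scale, with 606, 540 and 4763 CPM in L2427P and 215, 285 and 236 CPM in C1483Y. The 3 WT libraries lay at 1405, 541 and 466 CPM, and without L2427P replicate 3 the difference was 1.34. For that contrast 10 splits are too few for a share under 0.05, and 2 of them, the real one included, gave 1 call or more, with 1 as the highest of the others.

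The first pattern is that footprint library C1483Y replicate 3 was unlike the other footprint libraries. The tables argue against a poor library or other cells, since its median correlation with the others was 0.818 before the displacement, inside the 0.643 to 0.885 of the other footprint libraries. They argue against the genotype as well, since 0 windows of the other C1483Y footprint libraries were best matched at an offset. In 51 of 63 windows the values matched best at an offset of up to -60, with a median correlation of -0.00147 as deposited and 0.795 at the best offset, which is consistent with values displaced against the gene names. At which step this arose was not tested.

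The next pattern is the lower ribosomal protein mRNAs in L2427P. TMM normalization stays open, since DESeq2 size factors moved the median of all genes by only 0.04 in this contrast, too little for a test; 10 members were lower with them, adjusted over the list alone, 4 with TMM and 1 with DESeq2's Wald test. The sparse library L2427P replicate 3 may carry part of it, as the list lay -0.23 from the median of all genes without it and -0.34 with it, and it cannot be told apart from the genotype, because with other single libraries left out this distance ran from -0.50 to 0.13. The 10 splits of these libraries are too few for a share under 0.05, and the real split alone, 1 of 10, gave 4 members, with 3 as the highest of the others. Reads not aligned uniquely made up 60.7%, 64.5% and 77.5% in the L2427P mRNA libraries, against 56.4%, 58.1% and 62.4% in WT. Ribosomal protein genes have near-identical copies, and whether this share bears on their counts was not tested. The genotype stays open and was not tested apart from the libraries.

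The last pattern is the higher Adk footprints in the mutant libraries. A higher Adk mRNA level as the cause is argued against by a highest mutant level of 40.3 CPM, where 242 CPM would be needed for the footprint ratio of 7.65. This covers the mutant libraries in which Adk mRNA was detected, since it had 0 counts in C1483Y replicates 2 and 3 and L2427P replicate 3. Zeros and near zeros in libraries of few molecules may give such a pattern: 1.65% of 3753 genes of similar footprint level (62 genes, exact 95% interval 1.27% to 2.11%) had every mutant library above every WT library, where chance gives 1.79%. The bound set beforehand was weak, since zeros that fall at random over the libraries also give about the chance share, and a margin beyond the interval was added after the value was seen, so the zeros and the genotype cannot be told apart from this value. Chance stays open as well, with an adjusted exact permutation p of 0.393.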

How the results depend on the processing

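The fits with the displaced library, on the genes before the displacement, on abundant genes and with WT replicate 3 divided by 3, and all fits of footprints against mRNA, were chosen only after the data were seen. The cause of the changes below was not tested. DESeq2's Wald test called 172, 288, 269 and 502 mRNAs (C1483Y, L2427P and both mutants against WT, then L2427P against C1483Y), 804, 288, 702 and 504 footprint differences, 805, 541, 478 and 875 in translational efficiency, and 1617 for footprints against mRNA. In the mRNA of L2427P against WT, 1 ribosomal protein gene passed with it over the list alone. Counts of ribosomal protein genes below are for that mRNA contrast unless footprints against mRNA are named. There, 50 to 68 were lower over the list alone in all 26 alternatives. With DESeq2 size factors, 1 list test passed, mRNA calls were 0 between the mutants and 3 in L2427P, 10 ribosomal protein genes passed over the list alone, and there was 1 footprint call between the mutants and, in translational efficiency, 1 for both mutants and 2 for C1483Y. These factors moved the median of all genes by over 0.1 in 7 of 13 contrasts, from -0.23 to 0.15. Without a filter on low counts, 1 list test passed, with 2 footprint calls between the mutants and, in translational efficiency, 1 for both mutants, 2 between the mutants and 1 for L2427P. With the compared groups alone, mRNA calls between the mutants and ribosomal protein genes were 0 and 0, and translational efficiency gave 3 for C1483Y and 1 between the mutants. On abundant genes those first values were 0 and 0. TMM within each assay and WT replicate 3 divided by 3 each gave 1 translational efficiency call between the mutants. For footprints against mRNA, 36 genes were called with the displaced library as deposited, and 46 and 34 on the genes before the displacement with and without it.

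Whether the replicate numbers pair the samples stays open. Over 712 genes, libraries of the same number and assay deviated together with a mean correlation of 0.0317 (-0.0855 to 0.197). For libraries of the same assay with other numbers it was -0.0129 (-0.188 to 0.226). Between footprint and mRNA libraries of a genotype it was 0.000455 for the same number and -0.00103 for other numbers. At this spread between libraries, values near 0 cannot exclude a shared litter or day. With the replicate block, mRNA calls were 2 between the mutants and 3 in L2427P, ribosomal protein genes 21, footprint calls 1 between the mutants and 1 in L2427P, and translational efficiency calls 1 for both mutants, 3 for C1483Y, 1 between the mutants and 1 for L2427P, and 79 genes differed between footprints and mRNA. The library pair block gave 158.

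Leaving out 1 library at a time gave 0 to 1, 0 to 3, 0 to 2 and 0 to 3 mRNA calls in the order above, 0 to 13 ribosomal protein genes over the list alone, 0 to 153, 0 to 1, 0 to 152 and 0 to 125 footprint calls, 0 to 31, 0 to 4, 0 to 3 and 0 to 27 in translational efficiency, and 188 to 382 for footprints against mRNA, where 57 to 68 ribosomal protein genes were lower over the list alone. No named gene that was called changed sign. The calls of footprints against mRNA did change their balance, from 148 higher and 100 lower to 552 and 1065 with DESeq2's Wald test, 24 and 55 with the replicate block and 105 and 133 with TMM within each assay. Of 896 values of named genes under the alternatives, 728 kept their direction and side of the threshold, 129 no longer passed, 38 newly passed and 1 moved, and 2 more had no adjusted p from DESeq2. At this spread between libraries 0% of simulated 2-fold changes were recovered in mRNA and in footprints. The genes before the displacement hold no ribosomal protein gene of the list, so that count has no value there.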

Other observations

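The tests over other splits were planned before the data were examined, except that the contrast of footprints with mRNA was itself chosen only after the result was seen.

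Members of lists that were not called also differed between footprints and mRNA, averaged over the genotypes, by edgeR's quasi-likelihood test with adjustment over all genes. Of 23 chaperones 4 were higher in footprints and 0 lower, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.206), among them Hsp90aa1 at 2.45 (SE 0.24) and Hsph1 at 3.08. The other TOP translation genes went both ways, with 2 of 17 members higher and 5 lower, and 4 and 5 adjusted over the list alone (camera adjusted p = 0.611). The translation initiation factor Eif3a was at 2.60, the elongation factors Eef1a1 and Eef1b2 at -1.11 and -2.60, and Gnb2l1, a protein of the small ribosomal subunit, at -2.53. Tbr1, a transcription factor of deep-layer neurons, was at 2.63 (SE 0.65), and Akt1, a kinase upstream of mTOR complex 1, at -2.18. Mtor itself was at 2.65 (SE 0.26), with counts that include any reads from the construct.

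For footprints against mRNA, 1 of 100 drawn splits of the libraries, the real one, gave as many calls, with 248 in the real split and 30 as the highest of the others. This argues against a chance labelling of the assays for the count of calls, not for each called gene. The other splits mix the assays within a group, which adds any assay difference to the spread and can lower their counts. No such argument follows for the 1252 genes at unadjusted p below 0.05, a count that 14 of the 100 splits reached. Assay labels were permuted within each genotype. For mRNA in C1483Y against WT and L2427P against WT, and for footprints in L2427P against WT, 10 splits are too few for a share under 0.05, and the real counts were 0, 0 and 0, with 0, 1 and 1 as the highest of the others. For both mutants against WT, 84 of 84 splits for mRNA and 56 of 56 for footprints reached the real count of 0, as did 100 of 100 drawn splits for translational efficiency in L2427P and 100 of 100 for both mutants. Any split reaches 0, so these shares say nothing about chance, and the highest counts of the others were 3, 11, 5 and 12.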
